A study of Mus musculus with 3 samples.

How the data were processed

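The study used chromatin immunoprecipitation with sequencing (ChIP-seq), in which DNA bound to a protein is pulled down with an antibody and sequenced. Per the labels, D3 mouse embryonic stem cells were differentiated without serum in the presence of Activin A, a ligand of the Nodal-type receptors, into mesoendoderm cells. There were 3 libraries. Each of 2 was made with its own custom rabbit antibody against Brachyury, and 1 was a mock precipitation with pre-immune IgG. Per the labels, both rabbits received the same antigen, residues 249 to 436 of Brachyury fused to GST.

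The data used here were 1 list of 3160 regions for the whole series, with 3 columns and no header: chromosome, start and end, in base pairs. The deposited positions are the only values in the list. It holds no score, height, fold or p-value, and no value of a single library, so the antibodies could not be compared with each other or with the mock library, and the read depth behind each region is unknown. The labels assign 1 library to each antibody and to the mock, so there are no replicates within a group. Bowtie, MACS2 and the mouse genome build mm9 are named in the submitters' processing notes, with no version, role or setting. The deposited list is named as a common list. It was read as the regions found with both antibodies, but how the lists of both antibodies were combined, the thresholds and the use of the mock library are not given in the sources used here.

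The list was examined with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plotted with matplotlib 3.10.9. Starts were raised by 1 base, so that positions count from 1. No region was listed more than once (0 identical regions) and 0 neighbours overlapped. The gene table used here is on another assembly, GRCm38.p6, so it served only to count protein-coding genes per chromosome: 21631 on the autosomes and X. That the positions are not on GRCm38 was checked from the positions themselves. On chromosome 7, 8 regions lie beyond the last gene of that table. Regions were therefore not assigned to genes. Sets of genes (20) and of recognition sequences (29) fixed before the data were examined, and the planned tests of genomic location, gene sets and motifs, were not analysed here, because no mm9 genome or annotation was used. The rule for naming genes could not be applied for the same reason. The regions named in the text were chosen after their values were seen: the chains with the most members, the widest regions, the longest empty stretches and the regions on X.

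For each of 20 chromosomes, the share of regions was given with a Wilson 95% confidence interval and compared with the chromosome's share of protein-coding genes by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the 20 chromosomes. The main plan was a comparison with chromosome length, which needs the genome, and it set no test without one. Gene share, listed beforehand only as an alternative to length, was used in its place, so this test departs from the main plan. The span between the outermost regions of a chromosome was used as a further yardstick. Correlations across the 19 autosomes used 100000 permutations. Widths on X and on the autosomes were compared by a two-sided permutation test with 100000 permutations. Distances between adjacent midpoints were compared with 10000 random lists, in which the regions of each chromosome were placed uniformly between its outermost regions, or each region was shifted by up to 1 Mb. Where neighbours were merged first, the random lists were not merged in turn, so they could hold pairs closer than merged regions can. These comparisons are called permutation tests in the text, and for the two-sided p from 10000 lists the smallest possible value is 2.0e-04. Intervals and tests treat regions as independent and cover counting error only.

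The test of close neighbours against uniform placement and the chromosome test were run on simulated lists first. The shifts, merging, chains, widths and correlations were not simulated. The lists for the chromosome test drew regions independently, unlike the close neighbours of the real list. Of 100 lists placed uniformly, 4% gave p under 0.05 for close neighbours, and with 50 close pairs planted 100% did. In 500 lists drawn from the gene shares, 4.4% had any chromosome past the threshold, and X was called in 100% of lists when its share was set to 0.5 of its gene share. Alternatives were the merging of neighbours within 1 kb or 10 kb, the regions of at least the median width, the regions of at least 300 bp, other distances, gene counts without 1478 olfactory, vomeronasal and trace amine receptor genes, and the span yardstick.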

Results

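Brachyury is a T-box transcription factor needed for the formation of posterior mesoderm and the notochord. The study mapped the places it occupies in the genome of mesoendoderm cells, the common precursors of mesoderm and endoderm, derived from D3 mouse embryonic stem cells with Activin A. Chromatin was precipitated with 2 Brachyury antibodies, raised in different rabbits against the same antigen, and, as a mock, with pre-immune IgG, giving 1 library each. The measurement available for analysis was the deposited common list of 3160 regions on build mm9. It carries positions without signal values, so the error of each region could not be estimated, and occupancy was not compared between the antibodies or with the mock. All values below describe this single list.

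The regions covered 2.76 Mb of the genome in total. Their median width was 850 bp (95% confidence interval of the median 837 to 860 bp), with quartiles of 680 and 1019 bp, and their mean width was 875 bp (SD 299 between regions). Widths between 500 and 1200 bp accounted for 2646 regions, or 83.7% of the list (Wilson 95% interval 82.4% to 85.0%). The widest region lay on chromosome 17 at 39979840 to 39984019 and measured 4180 bp. It was 1.44 times as wide as the next, a region of 2910 bp on chromosome 14 at 106295864 to 106298773. Whether the region on chromosome 17 lies on a repeated sequence, such as a copy of the ribosomal RNA genes, which can give signal without binding, was not checked here. The third region by width, of 2537 bp, also lay on chromosome 14, at 117324007 to 117326543. Regions over 2000 bp numbered 15. At the other end, 45 regions (1.42%, Wilson 95% interval 1.07% to 1.90%) were narrower than 300 bp, of which 20 were narrower than 100 bp, and the narrowest measured 6 bp.

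Regions occurred on all 19 autosomes and on X, and 0 were listed on Y. Chromosomes 2 and 11 held the most, with 269 (8.51% of the list, Wilson 95% interval 7.59% to 9.54%) and 242 regions (7.66%, interval 6.78% to 8.64%). Chromosome X held 15 regions, or 0.475% of the list (interval 0.288% to 0.782%). Across the autosomes, the number of regions rose with the number of protein-coding genes. Pearson's r was 0.81 over the 19 autosomes (permutation p = 5.0e-05, adjusted over 3 relations p = 7.5e-05) and Spearman's rho was 0.90 (permutation p = 1.0e-05, the smallest that the permutations can give, adjusted p = 1.5e-05). Without chromosomes 7 and 2, the farthest from the median gene number, r was 0.93. Against gene counts without receptor genes, r was 0.88 (permutation p = 1.0e-05, adjusted p = 3.0e-05) and rho was 0.93 (permutation p = 1.0e-05, adjusted p = 1.5e-05). The number of regions also rose with the length of chromosome that they spanned, with r = 0.74 (permutation p = 2.6e-04, adjusted p = 2.6e-04) and rho = 0.77 (permutation p = 2.1e-04, adjusted p = 2.1e-04). Without chromosomes 1 and 19, r for the span was 0.73.

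**Figure D1:**
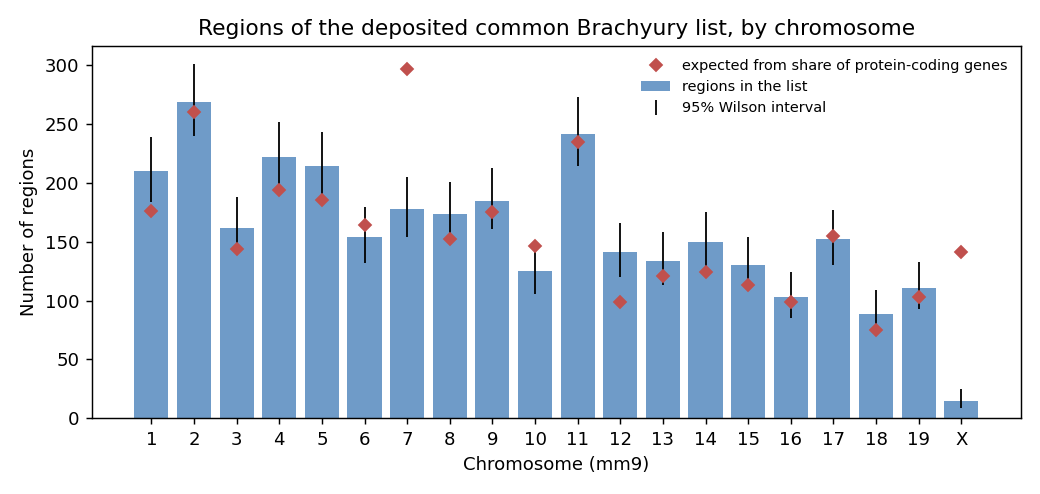
Number of regions in the deposited common list on each mm9 chromosome (bars, with Wilson 95% intervals of the count as lines) and the number expected from the chromosome's share of protein-coding genes (diamonds). X held 15 regions against 141 expected, and chromosome 7 held 178 against 297.

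Chromosome X carried far fewer regions than its genes would give. Its share of protein-coding genes corresponds to 141 regions, so the observed 15 were 0.106 of the expected number (95% interval 0.0645 to 0.175, exact binomial test, adjusted p = 2.5e-41). Per unit of length, X had 0.106 regions per Mb between its outermost regions. The autosomes ranged from 1.00 per Mb on chromosome 10 to 2.05 per Mb on chromosome 11, with a median of 1.31. The X regions were spread from 19645103 to 160695963. The longest empty stretch of X ran for 34.6 Mb, from 101183059 to 135754661, and the next for 25.03 Mb, from 19645905 to 44676582. For 15 regions placed at random over the same span, the longest distance averaged 32.8 Mb and was as long as the observed one at a one-sided permutation p of 0.351. On autosomes the longest was 19.1 Mb, on chromosome 10 at 51537105 to 70681976, followed by 16.9 Mb on chromosome 15 at 10653984 to 27559982.

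The regions on X were also narrower. Their median width was 659 bp (95% interval 548 to 726 bp, 15 regions) against 852 bp on the autosomes (interval 839 to 861 bp, 3145 regions), a difference of -193 bp (two-sided permutation test, p = 0.0155). All 15 X regions, with widths from 396 to 802 bp, were narrower than the autosomal median (two-sided Fisher's exact test, p = 5.9e-05). None of the 1582 regions of at least the median width lay on X (0 regions), which allows a share of up to 0.19%, taking a limit of 3 counts. Among the autosomes, median widths ran from 801 bp on chromosome 1 to 919 bp on chromosome 19.

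Among the autosomes, 3 departed from their gene share. The expected counts share the whole list over the autosomes and X, so the shortfall on X raises the ratio of every autosome, under either yardstick. Tests among the autosomes alone were not run, and a call close to the threshold, such as that of chromosome 1, may not hold in them. Chromosome 7 held 178 regions where 297 were expected, a ratio of 0.600 (95% interval 0.520 to 0.692, exact binomial test, adjusted p = 1.2e-13). Chromosome 12 held 141 where 99.2 were expected, a ratio of 1.42 (interval 1.21 to 1.67, exact binomial test, adjusted p = 3.5e-04). Chromosome 1 held 210 where 176 were expected, a ratio of 1.19 (interval 1.05 to 1.36, exact binomial test, adjusted p = 0.0466). This last call was lost without receptor genes (ratio 1.14, exact binomial test, adjusted p = 0.192) and among the regions of at least the median width (ratio 1.04, adjusted p = 0.779). The other 16 autosomes did not pass the threshold. The departures of chromosomes 7, 12 and 1 depended on the yardstick. Against the share of the spanned length, in the same exact binomial test, their ratios were 0.952 (adjusted p = 0.614), 0.958 (adjusted p = 0.648) and 0.881 (adjusted p = 0.0915), so the directions for chromosomes 12 and 1 turned. X remained low, at 0.0846 of its span share (exact binomial test, adjusted p = 2.0e-56).

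Neighbouring regions lay closer together than random placement gave. The median distance between adjacent midpoints was 306 kb (quartiles 97.8 and 835 kb, 3140 adjacent pairs). Within 10 kb of each other lay 162 pairs, 5.16% of the pairs, against a mean of 42.7 ± 6.40 (SD over 10000 random lists), a ratio of 3.79 (two-sided permutation p = 2.0e-04, the smallest that the random lists can give). The gap between neighbours was under 1 kb in 80 of the pairs and at its smallest 3 bp. With such neighbours merged, 81 pairs remained within 10 kb against 40.5 ± 6.23 at random, a ratio of 2.00 (permutation p = 2.0e-04). Each region was also shifted by up to 1 Mb in either direction, which keeps density differences over longer stretches but smooths those over about 1 Mb or less. After these shifts, 66.0 ± 7.92 pairs lay within 10 kb and the ratio for the deposited list was 2.45 (permutation p = 2.0e-04). With both the merging and the shifts it was 1.31 (permutation p = 0.0192). The random lists were not merged, so their counts lean high beside those of merged regions, and the ratios with merging lean low. Single regions with no neighbour within 50 kb numbered 2314, or 73.2% of the list.

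Chains of 3 or more regions, each within 50 kb of the next, numbered 77 and held 248 regions. Random placement gave a mean of 40.7 ± 10.9 regions in such chains, and at most 93 in 10000 lists (two-sided permutation p = 2.0e-04). Shifts of up to 1 Mb gave 104 ± 16.8 such regions (permutation p = 2.0e-04). With neighbours within 1 kb merged, chains held 183 regions, against 37.8 ± 10.6 at random and 94.1 ± 16.1 after shifts (permutation p = 2.0e-04 for each). Here too the random lists were not merged. The chain with the most members lay on chromosome 7 at 26022708 to 26102231, with 7 regions (6 after merging) over 79.5 kb and a median width of 743 bp. There were 3 chains of 5 regions. The most compact of these, on chromosome 2 at 152221736 to 152237346, spanned 15.6 kb and held 2 regions after merging. Another lay on the same chromosome at 70309748 to 70344507 and spanned 34.8 kb (4 after merging). The last lay on chromosome 11 at 69360050 to 69495906, spanned 136 kb and held 5 regions after merging too. Chains of 4 regions included 1 on chromosome 19 at 45797204 to 45821286 and 1 on chromosome 2 at 17948947 to 17986690, with median widths of 1027.5 and 1103 bp and, after merging, 3 and 4 regions.

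**Figure D2:**
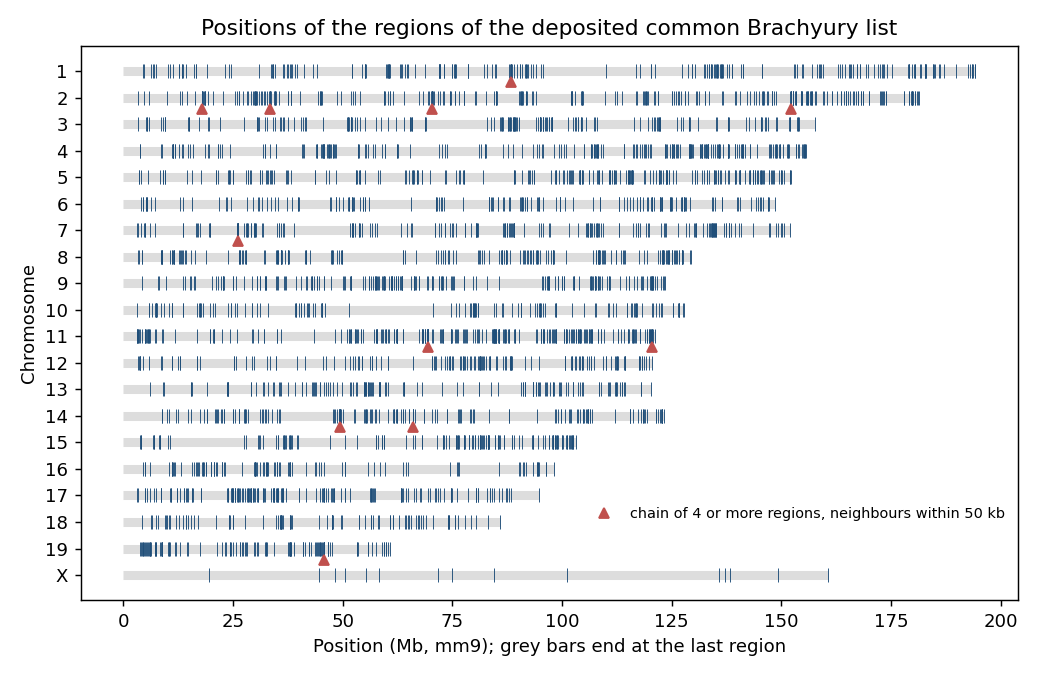
Position of each region of the list (vertical strokes) along each chromosome in Mb on mm9, with grey bars that end at the last region and triangles at the 11 chains of 4 or more regions. The X chromosome shows 15 strokes, and chromosome 2 holds 4 of the chains.

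**Figure D3:**
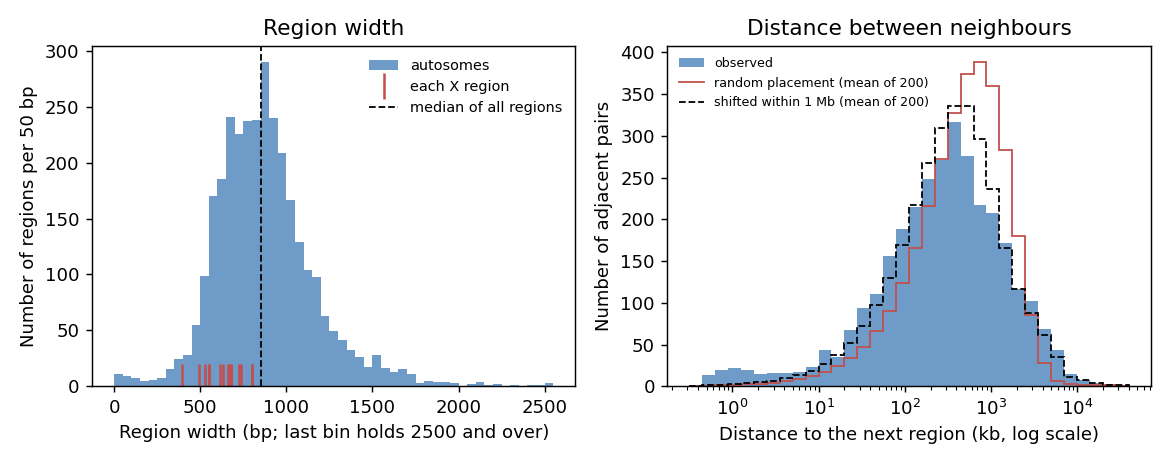
Left, number of regions per 50 bp of width on the autosomes, with a red stroke for each X region and a dashed line at the median of all regions, 850 bp. Right, number of adjacent pairs by distance in kb on a log scale, observed and as the mean of 200 random placements or of 200 lists with each region shifted by up to 1 Mb; the observed counts exceed both below 10 kb.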

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

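The regions of at least the median width were planned for the number of regions and the chromosome counts, as were the count of neighbours within 10 kb as 1 for the latter and the merging within 1 kb for number and width. The other alternatives, and the decision to test neighbour distance and width on X, came after the list had been seen. No paired analysis was possible because each antibody and the mock has 1 library and the list has no value per library. Other settings planned for genomic location, gene sets, T-box motifs and other motifs were not run, as they need an mm9 genome or annotation. Of 48 recomputed values, 40 kept their direction and their side of the threshold, stayed within the limits of their error or, for counts, stayed of similar size. Counts of chromosomes were judged by size alone, so a changed set of chromosomes could still pass. The number of regions was 1582 with the regions of at least the median width, as that choice fixes, and X then held 0% of them. The number of chromosomes past the threshold was 4 with gene share and 8 with span share, the latter being X and chromosomes 2, 3, 9, 10, 11, 17 and 19. It was 3 without receptor genes and 5 with the regions of at least the median width, where chromosomes 5 (ratio 1.28, exact binomial test, adjusted p = 0.0422) and 14 (ratio 1.33, adjusted p = 0.0455) were gained and chromosome 1 was lost. As X held none of these regions where 70.6 were expected, the autosomal ratios were raised, and both gains may partly restate the scarcity on X. With span share the ratio of chromosome 1 turned from 1.19 to 0.881 and that of chromosome 12 from 1.42 to 0.958; the cause was not tested. Chromosome 1 also missed the threshold without receptor genes. Chromosome 7 stayed past it without receptor genes (0.704, exact binomial test, adjusted p = 3.0e-06) and missed it with span share. The ratio on X lay between 0 and 0.113 in the 5 alternatives, with adjusted p of at most 1.6e-30. The ratio of close pairs to random ones ranged from 1.31 (permutation p = 0.0192), with neighbours within 1 kb merged and regions shifted by up to 1 Mb, to 5.71 for pairs within 5 kb. That of regions in chains ranged from 1.94 to 4.85. The difference in width on X ranged from -196 to -242 bp over 3 alternatives. Read depth is unknown, so regions missed for it could not be judged.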

Other observations

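Gene share was listed before the data were examined as an alternative to length, and its use as the main yardstick departs from the main plan. Its use to weigh the scarcity on X, and the tests of width on X and of the narrow regions, were chosen after the result was seen. The tests of the empty stretch on X, of the merging and shifting of neighbours and of width beside neighbours were chosen after the list had been seen but before their own results were.

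Once neighbours within 1 kb were merged, regions with company were slightly wider. Among regions that were not merged from several, the 693 with another region within 50 kb had a median width of 874 bp, against 841 bp for the 2314 without one, a difference of 33 bp (two-sided permutation test, p = 0.0108). The hypothesis that regions in company are wider passed its test among these regions, but the difference is small beside the SD of 299 bp between regions. The difference was not tested on the list as deposited, where 22 of the 45 regions under 300 bp had a neighbour within 1 kb. Such regions were left out of the comparison by the merging. Every region left out had company, while all 2314 regions without company stayed in. The difference may therefore come from this trimming, and it cannot show that regions in company are wider in general.

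The scarcity of regions on X has several candidate explanations. A low number of genes alone is argued against, since the upper 95% bound of the ratio to gene share was 0.175. That bound belongs to the same ratio that showed the scarcity and is no separate evidence. Outside its longest empty stretch, X had 0.141 regions per Mb with an upper bound of 0.232, below the lowest autosome at 1.00. The sparsity was thus not confined to that stretch. With so few regions, spread along X, this outcome was nearly fixed beforehand, so it cannot weigh the loss of blocks of X from the list. A weaker signal on X, for instance from fewer copies of X than of each autosome, may contribute. X regions were narrower in the median (a difference of -193 bp), which such a cause would give, but the list holds no signal and no copy number, so it cannot be told apart from fewer or weaker binding sites on X.

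The very narrow regions may come from how the list was made. If it holds the overlap of the peaks of both antibodies, a peak that spans a pair of peaks of the other antibody would leave close pieces, some of them slivers. Of the 45 regions under 300 bp, 22 (48.9%, Wilson 95% interval 34.96% to 63.0%) had a neighbour within 1 kb, against 131 of 3115 wider ones (4.21%, interval 3.56% to 4.97%; two-sided Fisher's exact test, p = 4.2e-18), consistent with an overlap of 2 peak lists. Whole peaks limited by a minimum peak length would pile up at 1 width, whereas the smallest width was held by 1 region and 20 regions lay under 100 bp. Under this hypothesis a width in the list is the shared part of a pair of peaks, not the width of a peak.

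How much of the excess of neighbours within 10 kb is such splitting stays open, since merging neighbours within 1 kb removes those pairs whether or not they were split. Splitting at that scale is argued against as the whole cause, as the ratio after merging was 2.00 (permutation p = 2.0e-04). Uneven density over stretches well beyond 1 Mb is argued against as the whole cause too. Against shifts of up to 1 Mb, merged regions had 1.31 times the random number (81 pairs against 62.1 ± 7.61, permutation p = 0.0192). The shifts smooth density over about 1 Mb or less, so they cannot weigh unevenness on that scale. Both ratios set merged regions against random lists that were not merged, so they do not measure the size of the remaining excess. A tendency of binding regions to lie in groups, uneven density on scales of about 1 Mb or finer and stretches to which reads cannot be mapped stay open.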
